A study of Mus musculus with 2 samples.

How the data were processed

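The series holds a pooled droplet library of sorted skin lymphocytes, sequenced in 2 runs that the labels call technical replicates. Per the labels, cells came from wild-type mice, from unwounded skin and from the edge of 4 mm dorsal punch wounds 3 or 5 days after wounding. A ring of 0.25 mm was digested in Liberase TL at 37 °C for 2.5 hours, and cells were stained with fluorescent and oligonucleotide-tagged antibodies and sorted. Hashtag 1 marks unwounded skin, hashtag 2 day 3 and hashtag 3 day 5, pooled at 1:1.5:1. The labels give no number of animals per pool. The authors made the count matrix with bcl2fastq and Cell Ranger on mm10 (GRCm38), with no versions given, and its values are raw UMI counts as deposited. Run 1 has the full matrix. Run 2 has only its barcode and feature lists here and was not analysed here beyond these lists.

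The matrix holds 17432 barcodes, 31053 genes and 9 antibody features, which are 3 hashtags and 6 surface tags (CD4, CD8b, CCR6, NKp46, TCR gamma-delta and TCR beta). It holds 129 M gene UMIs, with a median of 6070 UMIs and 1973 genes per barcode and 2.83% mitochondrial UMIs. The lowest depth of a barcode was 500 UMIs.

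Conditions were called from the hashtags. The plan was HTODemux of Seurat 5.3.0 in R 4.3.3, with k-means on centred log-ratio counts. On these data it set the cutoff of hashtag 2 at 1394 counts, inside the upper mode, and called 4577, 1019 and 4385 barcodes single with 5358 negative (30.7%). Several other settings were tried, and before any share or expression value was seen the main caller became a 2-component Gaussian mixture per hashtag on log10(count + 1) (scikit-learn 1.9.0), which had been listed beforehand as another caller. Its cutoffs were 62.9, 111 and 81.3 counts, and it called 3751, 5592 and 3168 barcodes single, 4551 multiplets (26.1%) and 370 negative (2.12%). Multiplets and negatives were left out. Cells needed at least 500 genes and at most 10% mitochondrial UMIs. Scrublet in scanpy 1.11.5, with an expected rate of 0.261 and its automatic threshold of 0.499, marked 2.80% of single-hashtag barcodes and 28.2% of multiplets. From barcodes with 2 hashtags, 16.1% of single-hashtag barcodes are predicted to be doublets within a hashtag, so most such doublets stayed in. After the filters 3394, 4892 and 2779 cells passed, and after Scrublet 3314, 4712 and 2713 cells were kept, with 18.0, 34.9 and 18.4 M UMIs and medians of 4732.5, 6567 and 5779 UMIs per cell.

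Counts were normalised per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (igraph 0.11.9) at resolution 1.0. Left out, 890 in all, were ribosomal, mitochondrial and receptor variable genes and those of the effector, hypoxia, glycolysis, cell cycle, stress and interferon lists. This was to keep the levels compared from defining the classes. List genes that are also cell type markers and no cytokines, Gzma among them, were not left out. The 26 clusters were named from 17 marker lists fixed, like the gene lists, the comparisons and the rule for naming genes, before the data were examined. A marker counted with at least 20 UMIs and a level 2-fold over the median cluster. A cluster took the name of the list with the largest share of counted markers, if at least 3 markers and 0.5 of the list counted and no list of another lineage reached a share of 0.8. It stayed unnamed if another list had more markers among its 10 highest genes, if it was shallow and had none of its own among them, or if a CD4 T name met a median CD4 tag count under 50. These limits were set over several passes after the clusters and their conditions had been seen, which changed whether clusters 16, 21 and 22 took a name. Clusters with no name are given by number. No cluster took the names of CD8 alpha-beta T, ILC3, NK or ILC1, B, neutrophil, endothelial, Schwann cells or melanocytes. In cluster 9 all 12 NK or ILC1 markers counted, but another list had more markers among its 10 highest genes. A separate clustering of the lymphoid cells was explored and not used. Surface tags were split by 2-component mixtures fitted on lymphoid cells, with cutoffs of 33.8 counts for TCR gamma-delta, 37.7 for TCR beta, 37.6 for CD4, 42.2 for CD8b, 47.5 for CCR6 and 3.34 for NKp46.

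Shares have exact binomial intervals. Within a class, UMIs were summed per condition and scaled to CPM, with exact Poisson intervals, at 95%. Ratios have exact conditional binomial intervals. They do not cover differences between animals or captures, for which 1 pool per condition gives no measure. No test or p-value was computed. Where a condition had 0 UMIs, the ratio is given as at least the value with 3 UMIs. Day 3 and day 5 were each compared with unwounded skin, and day 5 with day 3. Classes with at least 100 cells in both conditions were compared. The gamma-delta T class, with 99, 104 and 54 cells and 279815, 399454 and 211376 UMIs, falls short of this and was compared because the plan named it. In that class the 69 UMIs of Il17a in unwounded skin give 247 CPM with an interval of 192 to 312.

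Genes were named by a fixed rule. In the gamma-delta T class the 12 highest and 12 lowest genes of each wound day by log2((CPM + 5)/(CPM + 5)), and in the other classes the 4 highest and 4 lowest, were taken among genes with at least 50 CPM and 20 UMIs in the higher condition. Predicted genes, ribosomal, mitochondrial, receptor variable, haemoglobin and sex-linked genes were left out, and a fixed set of cytokine, receptor and transcription factor genes and leading list members was added. Of 19 functional lists the median log2 ratio of members with at least 20 UMIs over the pair is given where at least 3 were measured, with a 95% interval from 1000 Poisson redraws of the UMIs, and members are counted as higher or lower beyond 1.5-fold. Medians were also ranked among 10000 random lists matched on expression. For the gamma-delta T class at day 3 and day 5 the glycolysis median stood at percentiles 99.99 and 95.7, hypoxia at 96.9 and 94.5, interferon response at 99.9 and 99.9 and the type 17 cytokines at 10.3 and 0. Shares of cells with a UMI were taken after each cell was thinned to 2000 UMIs. Gene positions come from GENCODE vM21, which held all 184 named gene IDs.

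The CPM step was tested on simulated data. For 50 genes at each of 4 folds put into the gamma-delta T class at day 3, the median log2 ratios read back were 0.97, 1.92, −1.11 and −2.15 against true values of 0.94, 1.94, −1.06 and −2.06, and 94% to 98% of intervals held the true value. In the regulatory T class 90% to 100% and in the macrophage class 94% to 96% did. The class sums were drawn from Poisson laws, which the intervals assume, with no spread between cells. The simulation thus checks the computation alone. It cannot show how well the intervals hold where UMIs pile up in single cells.

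The alternatives were other hashtag callers, 2 other cell filters, doublets kept, 2 other Leiden resolutions, clustering with all variable genes, classes from surface tags, median-of-ratios scaling, other minimums for list members, thinned cells and the largest cluster of a class alone. Chosen after the data were seen were HTODemux with clara, a stricter Scrublet score of 0.319, gamma-delta T cells with the receptor tag alone, sums without the top cell of each gene, and clusters 5 and 8 counted as dendritic-like. The split of cytokines by receptor tag, its values with a class left out and the interferon subtraction in both conditions were chosen then as well. In re-clustered data each cluster took the class most of its cells had, which kept 89.4% to 96.6% of cells in their class. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, umap-learn 0.5.12, scikit-image 0.26.0 and matplotlib 3.10.9, and Matrix 1.6.5 in R, were used.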

Results

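Mouse skin lymphocytes were profiled by CITE-seq (droplet sequencing of RNA together with barcoded antibodies) in 3 conditions: unwounded skin, the wound edge at day 3 and the wound edge at day 5. Wounds of 4 mm were made with a punch in the dorsal skin of wild-type mice, a ring of 0.25 mm around the wound was digested, and live cells were sorted as CD45.2+ CD90.2+ TCR Vγ3−. The gate was therefore set for T cells and innate lymphoid cells and against the Vγ3+ dendritic epidermal T cells. Each condition carried its own antibody hashtag, and the 3 were pooled at 1:1.5:1. Of 17432 barcodes, 12511 carried a single hashtag, and 10739 cells were left after filtering for genes, mitochondrial share and doublets: 3314 from unwounded skin, 4712 from day 3 and 2713 from day 5. Their median depths were 4732.5, 6567 and 5779 UMIs. Each condition was 1 pool with no replicates, so animals cannot be told from one another, and the ranges in parentheses are 95% intervals that cover counting error only. They are exact, except for list medians, where they come from Poisson redraws of the UMIs. Expression is given in CPM (counts scaled to the total UMIs of the class in that condition), and cell classes named from their RNA are called "-like".

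Myeloid cells made up most of every condition despite the CD90.2 gate, and their makeup differed strongly between unwounded and wounded skin. Macrophage-like cells were 20.5% (19.2 to 21.97) of kept cells in unwounded skin, 54.8% (53.3 to 56.2) at day 3 and 48.4% (46.5 to 50.3) at day 5, so their share was 2.66 times (2.45 to 2.90) and 2.36 times (2.15 to 2.59) as high in the wounds. Dendritic-like cells went the other way, with 52.4% (50.6 to 54.1), 10.1% (9.26 to 10.998) and 11.6% (10.4 to 12.9). Cluster 5, counted as macrophage-like, and the unnamed cluster 8 hold markers of both classes, 9 and 10 of 10 for macrophages and 7 and 6 of 8 for dendritic cells. With both counted as dendritic-like, a grouping chosen after the data were seen, dendritic-like cells were 52.9%, 24.5% and 28.2% and macrophage-like cells 20.3%, 46.2% and 37.7%. The macrophage marker Lyz2 stood in dendritic-like cells at 105% of its macrophage-like level in unwounded skin. In the wounds it stood at 27.2% and 27.0%. Cluster 3, the main dendritic-like cluster of unwounded skin, counted 7 of 8 dendritic markers, and counting it otherwise was not tried. The cells behind each name differed as well. In unwounded skin 629 of 681 macrophage-like cells lay in cluster 13, led by Ccl8, Cd209f, F13a1 and Pf4, while the wound cells lay mostly in clusters 2, 4, 5 and 10, the last led by Lpl, Thbs1 and Trem2. Dendritic-like cells of unwounded skin were mostly cluster 3 (896 of 1735), led by Retnla, Mucl1 and Cd209a, while in the wounds cluster 1 was the largest without holding most of them (193 of 476 at day 3, 82 of 315 at day 5). It was led by the Langerhans cell gene Cd207 and by Mfge8. Cluster 8, a myeloid cluster led by Ear2, Ccl17 and Cd209e that took no name, was 0.332% of unwounded, 5.84% of day 3 and 5.90% of day 5 cells. Mast-like cells were 0.151%, 0.361% and 1.77%. Cells of lymphoid clusters were 21.8% (20.4 to 23.3), 20.8% (19.7 to 22.03) and 25.8% (24.2 to 27.5), that is 723, 982 and 700 cells. The sort gate and the digestion can set all of these shares. Clusters 19, 21 and 22, which took no lineage name, were kept out and held 0.272%, 0.0302% and 0.634% of unwounded cells, 1.46%, 1.74% and 1.53% at day 3, and 2.06%, 0.848% and 1.44% at day 5.

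**Figure D1:**
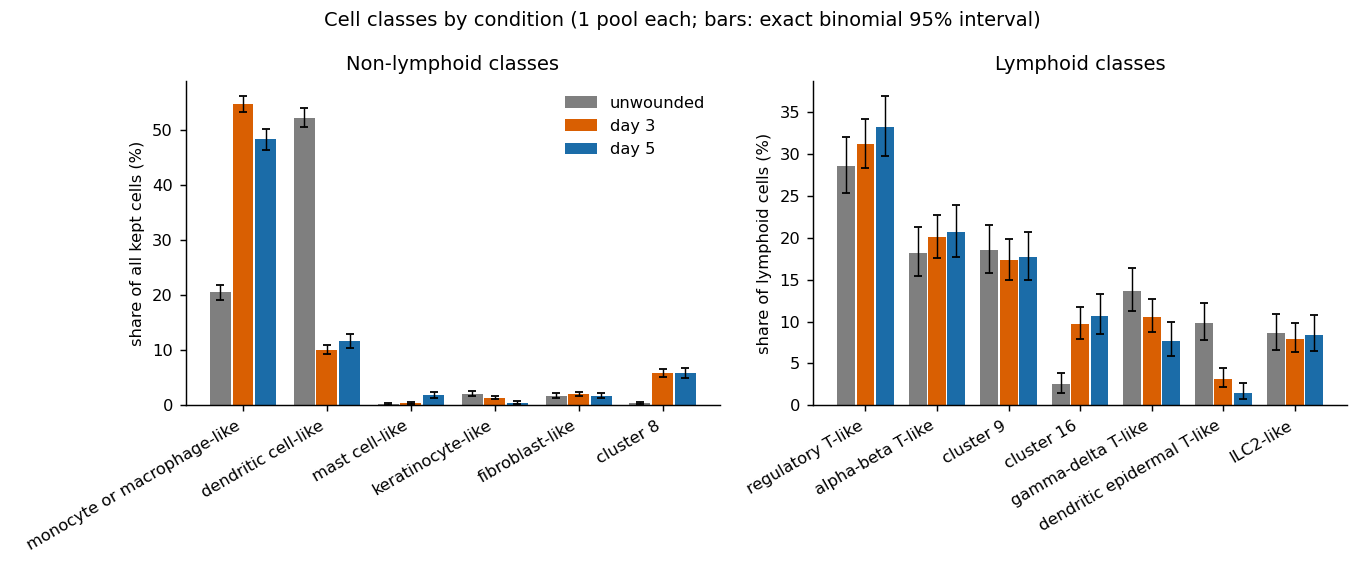
Bars give the share of each myeloid, stromal and unnamed class among all kept cells (left, %) and of each lymphoid class among lymphoid cells (right, %) in unwounded skin and at day 3 and day 5, with exact binomial 95% intervals. Macrophage-like cells were 20.5%, 54.8% and 48.4%, dendritic-like cells 52.4%, 10.1% and 11.6%.

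Within the lymphoid compartment gamma-delta T-like cells made up a smaller part at day 5 than in unwounded skin. Cells of the gamma-delta T-like class (cluster 17, led by Trdc, Cxcr6, Il17a and Cd163l1) were 13.7% (11.3 to 16.4) of lymphoid cells in unwounded skin, 10.6% (8.74 to 12.7) at day 3 and 7.71% (5.85 to 9.95) at day 5. The ratio to unwounded skin was 0.773 (0.582 to 1.03) at day 3, an interval that includes 1, and 0.563 (0.397 to 0.793) at day 5. Dendritic epidermal T-like cells, which the gate was set against, were 9.82% (7.75 to 12.2), 3.16% (2.15 to 4.45) and 1.43% (0.687 to 2.61), though at day 3 their log2 ratio of −1.64 was 0.22 with the k-means hashtag caller. Read from the antibodies alone, lymphoid cells with the TCR gamma-delta tag and without the TCR beta tag were 24.3% (21.3 to 27.6), 14.5% (12.3 to 16.8) and 8.29% (6.35 to 10.6). This gate takes in dendritic epidermal T-like cells, and the 2 RNA classes together were 23.5% (20.5 to 26.8), 13.7% (11.7 to 16.1) and 9.14% (7.11 to 11.5). Cells with the TCR beta and CD8b tags were 4.15% (2.82 to 5.87), 7.23% (5.69 to 9.03) and 12.4% (10.1 to 15.1), and those with the TCR beta and CD4 tags were 43.0%, 47.3% and 51.1%. Cluster 16, a T cell cluster that took no name because its CD4 tag spoke against it, was 2.49% (1.48 to 3.91), 9.67% (7.90 to 11.7) and 10.7% (8.52 to 13.2). It had no counterpart in 7 of 10 alternative clusterings, where its cells joined other classes. Regulatory T-like cells, at 28.6%, 31.3% and 33.3%, alpha-beta T-like cells at 18.3%, 20.1% and 20.7%, cluster 9 at 18.5%, 17.3% and 17.7%, and ILC2-like cells at 8.58%, 7.94% and 8.43% held near equal shares with the main settings. With at least 1000 genes and at most 5% mitochondrial UMIs per cell the ILC2-like share was lower in the wounds, with log2 ratios of −0.92 and −1.20, and the regulatory T-like share higher, at 0.67 and 0.53. The ILC2-like share at day 5 was also lower with doublets kept (−0.62) and with the stricter doublet filter (−0.68), and 3 other clusterings had no counterpart of the class. With the k-means caller the regulatory T-like share at day 3 was 0.74.

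In the gamma-delta T-like class the wounded skin carried much more Areg, more Il17a at day 3, and less Tnf and Csf2. Il17a, which encodes interleukin 17A, stood at 247 CPM in unwounded skin, 576 at day 3 and 454 at day 5, which is 2.33-fold (1.78 to 3.10) and 1.84-fold (1.34 to 2.55) higher. Areg, the growth factor amphiregulin that binds the epidermal growth factor receptor, stood at 189, 1562 and 619.7 CPM, 8.25-fold (6.22 to 11.1) and 3.27-fold (2.36 to 4.59) higher. At day 3 a single cell held 216 of its 624 UMIs; without the top cell of each condition the ratio was 7.52 (5.39 to 10.8). Il17f, the relative of Il17a beside it on chromosome 1, stood at 239, 323 and 156 CPM, 1.35-fold (0.996 to 1.84) and 0.652-fold (0.416 to 1.00). Tnf, which encodes tumour necrosis factor, was 2.52-fold lower at day 3 (1.70 to 3.77) and 14.0-fold lower at day 5 (5.23 to 52.6), from 264 CPM to 105 and 18.9. Csf2, which encodes the growth factor GM-CSF, had 21 UMIs in unwounded skin, 10 at day 3 and 0 at day 5, where it was at least 5.29-fold lower. Hif1a, the oxygen-regulated transcription factor subunit, was level at day 3 (297 against 305 CPM, 1.03-fold, 0.773 to 1.38) and lower at day 5 (189 CPM, 0.638-fold, 0.426 to 0.941). Il23r, the receptor chain for interleukin 23, stood at 179, 135 and 94.6 CPM (0.757-fold, 0.505 to 1.13, and 0.530-fold, 0.299 to 0.906). The interleukin 1 receptor Il1r1, at 100, 70.1 and 75.7 CPM, and Gata3, a type 2 transcription factor, at 46.5, 55.1 and 75.7 CPM, had intervals on both sides of 1. Between the wound days, day 5 was 2.07-fold lower than day 3 for Il17f (1.40 to 3.13), 2.52-fold lower for Areg (2.08 to 3.07), 1.61-fold lower for Hif1a (1.12 to 2.37) and 0.789 times day 3 for Il17a (0.615 to 1.01).

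The Il17a difference did not rest on single cells, which held at most 16 of 69, 30 of 230 and 17 of 96 UMIs, but its size at day 5 depended on which cells joined the class. Thinned to 2000 UMIs per cell, 13.3% (6.81 to 22.5) of gamma-delta T-like cells held an Il17a UMI in unwounded skin, 31.3% (22.4 to 41.4) at day 3 and 30.8% (18.7 to 45.1) at day 5, after 16, 5 and 2 shallower cells were left out. Unthinned, these shares were 19.2%, 32.7% and 33.3%, at median depths of 2659, 3663 and 3740 UMIs. Thinned dendritic-like cells, which should lack Il17a, had no Il17a UMI in any of 1688, 470 and 311 cells, and unthinned 1 cell had one, in unwounded skin. This bounds how often a UMI is detected, not how many cells express the gene. By the receptor tags the class was not pure, though the TCR beta cutoff lies below the background of macrophage-like clusters, as given below. Cells with the TCR beta tag alone were 7 of its 99 cells in unwounded skin, 25 of 104 at day 3 and 13 of 54 at day 5, and held 1 of 69, 20 of 230 and 40 of 96 Il17a UMIs. Among cells of the class with the TCR gamma-delta tag alone the log2 ratio of Il17a was 1.97 at day 3 and 1.11 at day 5, against 1.21 and 0.87 over the whole class. Over the whole class the day 5 ratio was 0.25, 0.00 and 0.07 with 3 other settings of hashtag calling, cell filter and doublet removal, and −0.18, −0.15 and −0.40 with 3 more, so the day 5 gain within the class is not firm. With the k-means hashtag caller, which kept 826 cells of day 3, the day 3 ratios of Il17a and Areg turned to −6.44 and −5.31. Few of those cells were gamma-delta T-like, since the lymphoid and gamma-delta T-like shares were lower too. They held under 20 Il17a UMIs, and the ratios have 5 CPM added. Values this low can come from an absence of counts and do not measure a fall. With it day 5 was also higher than day 3 for Il17f, by 0.13, and for Areg, by 6.53. The genes lie on GRCm38 (GENCODE vM21) at chromosome 1:20730905-20734496 for Il17a (ENSMUSG00000025929), 1:20777146-20790617 for Il17f (ENSMUSG00000041872), 5:91139599-91148432 for Areg (ENSMUSG00000029378), 17:35199381-35202007 for Tnf (ENSMUSG00000024401), 11:54247271-54249667 for Csf2 (ENSMUSG00000018916) and 12:73901375-73947530 for Hif1a (ENSMUSG00000021109).

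**Figure D2:**
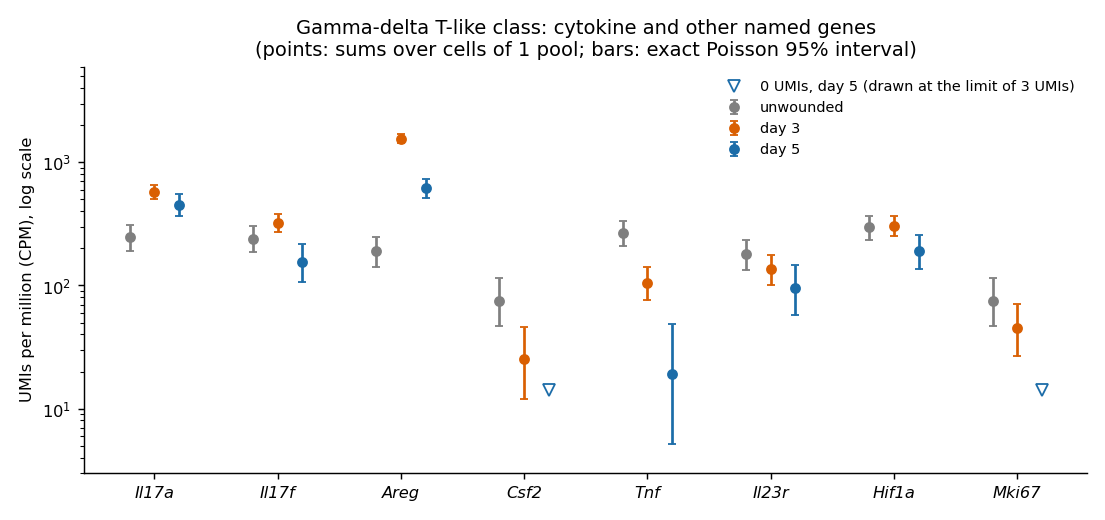
Points give the level (CPM, log axis) of Il17a, Il17f, Areg, Csf2, Tnf, Il23r, Hif1a and Mki67 in the gamma-delta T-like class of each condition, with exact Poisson 95% intervals; open triangles mark 0 UMIs and are drawn at the limit of 3 UMIs. Areg stood at 189, 1562 and 619.7 CPM and Il17a at 247, 576 and 454.

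Beyond the cytokines, the gamma-delta T-like class of the wounds carried more transcripts of Hspa1a, Calca and Sgip1. At day 3 the 12 genes that ranked highest included Hspa1a and Hspa1b, heat-shock proteins, 13.8-fold (6.85 to 32.6) and 9.89-fold (4.85 to 23.5) higher, Calca, which encodes the peptide CGRP and calcitonin, 14.2-fold (4.65 to 71.0) higher, and Id3, an inhibitor of E proteins, 11.4-fold (3.69 to 57.4) higher. Sgip1 was 10.2-fold (3.76 to 38.5) higher, the interferon-induced Isg15 10.7-fold (3.45 to 54.0), the DNA glycosylase Neil1 14.0-fold (2.24 to 581), the leukotriene receptor Cysltr1 8.17-fold (2.58 to 41.5), Zdhhc23 7.47-fold (2.34 to 38.1) and the granzyme Gzmc 5.92-fold (2.96 to 13.4). Areg was among them, and so was Tff1, a secreted trefoil peptide, at least 5.84-fold higher but with all 25 UMIs in 1 cell. At day 5 Sgip1 and Calca were again high, 18.5-fold (6.85 to 70.4) and 16.8-fold (5.32 to 84.9), with Pmepa1, a target of TGF-beta signalling, 9.05-fold (3.82 to 26.1), the phosphatase Dusp10 8.94-fold (3.11 to 35.1), and the glycolytic enzyme Tpi1 6.62-fold (2.22 to 26.6). Higher as well were Coq8a 6.62-fold (2.22 to 26.6), Mvk of the sterol pathway 5.74-fold (2.31 to 17.04), Hspa1a 5.46-fold (2.47 to 13.7), AW112010 5.30-fold (1.93 to 18.1), Rasgrp2 5.05-fold (2.56 to 10.9) and Rusc1 5.00-fold (2.35 to 11.9). Penk, the proenkephalin gene, was 43.7-fold (7.31 to 1777) higher at day 5 with 33 UMIs in 1 cell, and was lower with 4 other settings. With the k-means caller most of these day 3 values changed sign: Calca and Sgip1 to −2.30, Id3 to −3.61, Gzmc to −2.60, Cysltr1 and Zdhhc23 to −1.93 and Neil1 to −1.43, while Hspa1a stayed higher at 1.21, Hspa1b at 0.66 and Isg15 at 2.06. These values rest on few day 3 cells, and the negative ones can come from an absence of counts.

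Among the genes that were lower in the wounded gamma-delta T-like class were an adhesion receptor, an inhibitor of cell death and genes of dividing cells. At day 3 the adhesion receptor Adgre5 (CD97) was 9.28-fold (4.38 to 22.6) lower, the clock repressor Nr1d1 4.64-fold (2.04 to 11.9), the membrane protein Emp1 4.19-fold (2.34 to 7.92), Stk40 4.10-fold (1.77 to 10.6) and the metalloprotease Adam8 4.04-fold (2.74 to 6.09). Fbxo30 and the retinoic acid receptor Rarg were both 3.93-fold (1.68 to 10.2) lower, Xpo6 3.75-fold (1.59 to 9.78), Hbp1 3.69-fold (2.07 to 6.90), the bicarbonate transporter Slc4a7 3.62-fold (1.86 to 7.50) and Cflar, an inhibitor of caspase 8, 3.35-fold (2.35 to 4.84). The tight junction gene Cldn5 had 20 UMIs in 3 unwounded cells and 0 at day 3, at least 9.52-fold lower, and was 15.1-fold (2.42 to 626) lower at day 5, though higher there with 2 other settings. At day 5 Hist1h2ap, a histone gene of dividing cells, was 9.67-fold (3.93 to 30.8) lower, the p53 antagonist Mdm2 8.06-fold (2.52 to 41.1), the transcription factor Elk4 7.55-fold (2.35 to 38.7), and Nup153 7.55-fold (1.84 to 66.7). Lower as well were Emp1 7.10-fold (2.84 to 22.9), Cyth2 6.99-fold (2.51 to 27.0), the immediate early gene Jun 6.61-fold (2.36 to 25.6) and the linker protein Plec 5.72-fold (3.26 to 10.8). Jun was higher with the stricter cell filter, by 0.30 log2, and Rarg at day 3 with the k-means caller, by 0.68. Mki67, a marker of dividing cells, stood at 75.0, 45.1 and 0 CPM, 0.600-fold (0.302 to 1.18) at day 3 and at least 5.29-fold lower at day 5, but its 21 unwounded UMIs lay in 3 cells and the ratio at day 5 was 0.06 log2 with the looser cell filter.

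Of the gene lists fixed beforehand, glycolysis, interferon response and regulatory T effector genes were higher in wounded gamma-delta T-like cells. The median glycolysis member was higher by 0.51 log2 (0.21 to 0.68) at day 3, where 5 of 13 measured members (Tpi1, Slc16a3, Eno1, Ldha and Pfkl) were at least 1.5-fold higher and 0 lower, and by 0.20 (0.00 to 0.46) at day 5, with 3 of 12 higher. Hypoxia genes and targets of HIF were higher by 0.28 (0.02 to 0.59) at day 3, with 3 of 8 higher (Bhlhe40, Ldha and Egln3), and by 0.26 (−0.17 to 0.56) at day 5, with 1 of 7 higher and 1 lower. Among cells with the TCR gamma-delta tag alone the hypoxia median at day 3 was 0.01. Interferon response genes were higher by 0.59 (0.24 to 1.01) and 0.79 (0.33 to 1.17), with 4 of 8 and 4 of 6 members higher, Bst2 and Ly6a among them on both days. The day 3 median was −0.04 with the k-means caller. The list of regulatory T effector genes was higher by 0.97 (0.56 to 1.20) and 1.21 (0.81 to 1.41), with 4 of 6 and 5 of 7 higher, Tnfrsf9, Tnfrsf18, Ikzf2 and Icos on both days, and Il2ra lower. These medians were 0.07 and 0.32 with the k-means caller. The type 17 cytokine list split: with Il17a higher and Csf2 and Tnf lower, its median of 4 members was −0.43 (−0.70 to 0.05) at day 3 and −2.05 (−2.53 to −1.48) at day 5, and with every member that had 1 UMI in each condition it was 0.42 and 0.08. From day 3 to day 5 its 3 measured members had a median of −1.03. Proliferation genes were lower by 0.48 (−0.76 to −0.08) and 0.92 (−1.51 to −0.50), with 4 of 8 and 3 of 6 lower; with the looser cell filter these became 0.15 and 0.34, and with the 5-fold hashtag rule the former was 0.06.

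Of the other lists in the gamma-delta T-like class, recirculation stood out at day 5, with few members measured. Medians at day 3 and day 5 were 0.21 and −0.33 for the type 17 programme, with Il17re and Maf higher at day 3 and Il23r lower at day 5, 0.22 and 0.24 for oxidative phosphorylation, and 0.24 and 0.33 for tissue residence, where Ramp1, Itgae, Crem and Rgs1 were higher on both days. Recirculation genes had medians of −0.53 (−0.98 to 0.07) and −1.41 (−2.10 to −0.55) over 3 members, with Klf2, the transcription factor of recirculating T cells, lower and Ccr7 higher. Medians were 0.29 and 0.06 for skin and wound homing receptors, with Ccr2 and Cxcr4 higher on both days, 0.17 and −0.16 for immediate early and dissociation stress genes, −0.05 and −0.31 for tissue repair factors, where Areg alone of 3 was higher, and −0.28 and 0.26 for lipid uptake and metabolism. Too few members were measured for the lists of type 1 and cytotoxic genes (1), type 2 genes (2), exhaustion and checkpoint genes (2), sex-linked genes (2 at day 3 and 1 at day 5) and haemoglobin (0). At day 5 the median of all genes in this class was itself −0.19 log2, and the median-of-ratios scaling would add 0.14 to the day 3 values. RNA at the level of macrophage genes made up 1.54%, 1.15% and 1.53% of the class. With the k-means caller the day 3 medians of tissue residence and of immediate early genes were −0.15 and −0.71, and with clara the day 5 median of the type 17 programme was 0.01.

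**Figure D3:**
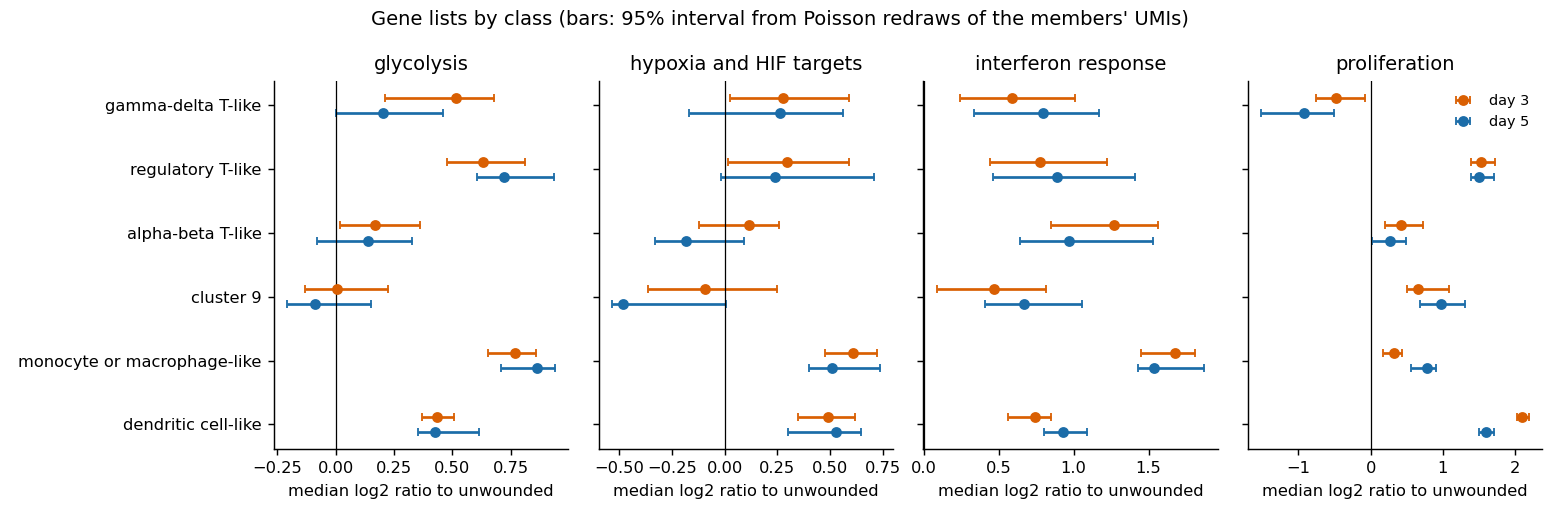
Points give the median log2 ratio to unwounded skin of the measured members of 4 gene lists in 6 classes at day 3 and day 5, with 95% intervals from Poisson redraws of the UMIs. The proliferation median was 1.53 and 1.51 in regulatory T-like cells and −0.48 and −0.92 in gamma-delta T-like cells.

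Read by the T cell receptor tag, Il17a and Il17f transcripts came mostly from cells with the TCR gamma-delta tag in unwounded skin and at day 3, and mostly from cells with the TCR beta tag at day 5. Of the Il17a UMIs in lymphoid cells, those with the TCR gamma-delta tag alone held 66.9% (57.7 to 75.3) of 118 in unwounded skin, 82.7% (78.4 to 86.4) of 369 at day 3 and 32.5% (25.5 to 40.2) of 166 at day 5. Cells with the TCR beta tag alone held 5.93% (2.42 to 11.8), 16.8% (13.1 to 21.02) and 64.5% (56.7 to 71.7) of the Il17a UMIs. At day 5 this was spread over CD4+ cells (26.5%), CD8b+ cells (20.5%) and cells with neither or both of these tags (17.5%). They were 25 cells in all, with at most 16 UMIs in any. Tag and RNA class differ here, since 40 of the 107 beta tag UMIs of Il17a at day 5 and 15 of the 97 of Il17f lay in cells of the gamma-delta T-like class, 16 of the former in 1 CD8b+ cell. Outside that class beta tag cells held 67 of 70 and 82 of 92. For Il17f the gamma-delta tag held 76.5%, 78.7% and 13.6% (8.13 to 20.9) and the beta tag 6.17%, 13.5% and 77.6% (69.3 to 84.6). Part of this follows from cell numbers, since cells with the gamma-delta tag were 176, 142 and 58. Il17a stood at 167 (132 to 208), 632 (563 to 707) and 259 (195 to 338) CPM in gamma-delta tag cells and at 6.35 (2.55 to 13.1), 21.7 (16.7 to 27.8) and 44.1 (36.1 to 53.3) CPM in beta tag cells. Il17f stood at 131, 253 and 81.6 CPM in the former and 4.53, 7.36 and 40.0 in the latter. The gamma-delta tag cells include 64, 31 and 10 dendritic epidermal T-like cells with no Il17a UMI, which lower the unwounded level most. Without them Il17a stood at 254 (201 to 316), 768 (685 to 860) and 298 (224 to 389) CPM and Il17f at 190 (144 to 244), 307 (255 to 367) and 93.9 (54.7 to 150). So among these cells Il17a was higher at day 3, and at day 5 its interval overlapped that of unwounded skin. Of the 79 unwounded Il17a UMIs of gamma-delta tag cells, 31 lay in cluster 16, most of them in 1 cell. The unwounded level and share, and so the overlap at day 5, lean on that cell. Values without it were not computed. The day 5 shares of the beta tag stayed between 57.3% and 65.3% for Il17a and between 74.0% and 77.6% for Il17f over 7 other settings. In unwounded skin cells with no receptor tag held 22.03% of the Il17a UMIs, and the gamma-delta share there ran from 45.1% with the k-means caller to 80.6% with another caller. The split by tag, and its values with a class left out, were chosen after the class values had been seen.

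**Figure D4:**
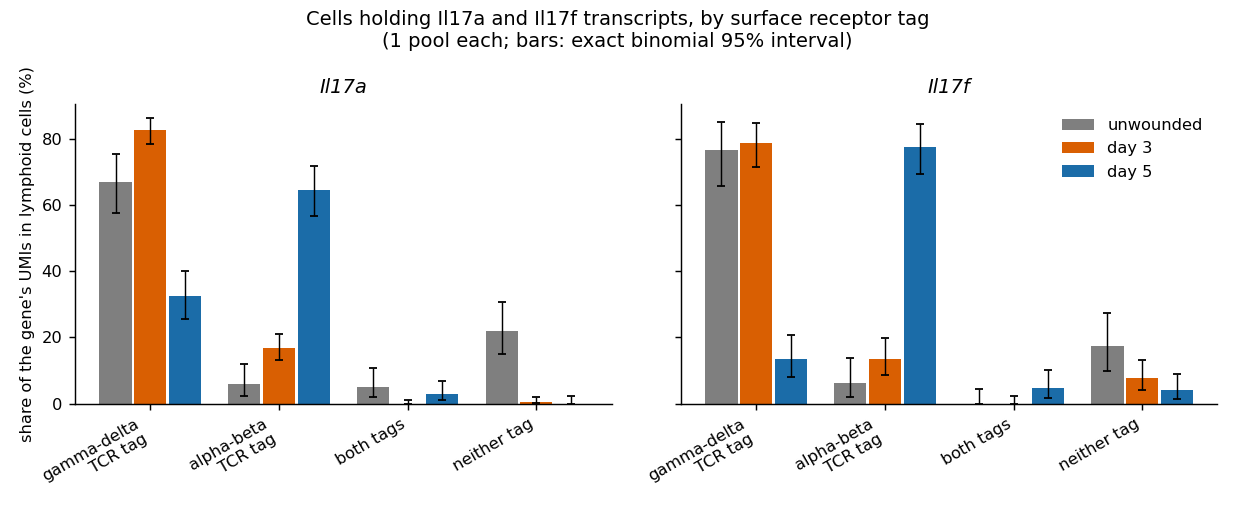
Bars give the share (%) of the Il17a and Il17f UMIs of lymphoid cells held by cells with the TCR gamma-delta tag, the TCR beta tag, both or neither, by condition, with exact binomial 95% intervals. The gamma-delta tag held 66.9%, 82.7% and 32.5% of the Il17a UMIs, and the beta tag 5.93%, 16.8% and 64.5%.

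By RNA class, the day 5 sources of the type 17 cytokines were several. Of all Il17a UMIs (119, 395 and 176), the gamma-delta T-like class held 58.0%, 58.2% and 54.5%, cluster 16 held 30.3% (27 of 36 UMIs in 1 cell), 26.1% and 5.68%, and regulatory T-like cells 1.68%, 6.33% and 18.2%. Where cluster 16 had no counterpart, the gamma-delta T-like class held 85.2% to 92.2% in unwounded skin. In cluster 16 itself, cells with the gamma-delta tag were 9 of 18, 23 of 95 and 7 of 75. Of Il17f the gamma-delta T-like class held 80.7%, 77.7% and 24.8% (17.7 to 33.0), and the ILC2-like class 6.02%, 9.64% and 40.6% (32.2 to 49.5). Cluster 16 held 18.8% at day 5. By the TCR beta tag, with the same limit of its cutoff, the ILC2-like class was not pure at day 5. Then 42.4% of its cells had the tag against 20.97% and 15.4% before. Outside the gamma-delta T-like class, 82 of 92 day 5 Il17f UMIs of lymphoid cells lay in beta tag cells. So most Il17f UMIs of the ILC2-like class then lay in such cells. Its day 5 Il17a UMIs were 11 in CD4+ and 6 in CD8b+ beta tag cells, and 0 in its 34 cells with no receptor tag. Il22, the epithelial growth cytokine of type 17 cells, had 4, 39 and 88 UMIs, and cluster 16 held 59.0% at day 3, with 22 of 23 UMIs in 1 cell, and 97.7% at day 5. All 88 UMIs of day 5 lay in 7 cells with the TCR beta tag, 39 of them in 1 cell. Il22 lies at chromosome 10:118204942-118210047 (ENSMUSG00000074695).

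Of the other effector cytokines, Ifng and Il5 kept their main RNA class, while that of Csf2 at day 5 was another. Ifng, the type 1 cytokine interferon gamma, had 90, 331 and 187 UMIs, of which cluster 9 held 48.9%, 53.2% and 66.8% and alpha-beta T-like cells 33.3%, 13.9% and 15.5%. Il5, which sustains eosinophils, came almost wholly from ILC2-like cells, with 86.8%, 90.9% and 95.4% of 266, 594 and 350 UMIs. For Il13, another type 2 cytokine, ILC2-like cells held 70.8%, 53.7% and 37.0%, and mast-like cells held 18.6% at day 3 and 44.6% at day 5. At day 5 a single cell held 32 of the 82 UMIs of mast-like cells, and without the top cell of each class they had 50 against 52 in ILC2-like cells. The leading genes of the mast-like cluster also include Mcpt8 and Prss34, which basophils express. Csf2 came from ILC2-like cells (43.5%, 43.4% and 26.0%) and, at day 5, from mast-like cells (52.6%), while the gamma-delta T-like share went from 33.9% to 3.58% and 0. Areg was shared widely: dendritic epidermal T-like cells held 31.3% in unwounded skin, and in the wounds macrophage-like cells held 23.4% and 26.9%, regulatory T-like cells 20.6% and 21.2%, ILC2-like cells 14.9% and 15.7% and gamma-delta T-like cells 12.02% at day 3. The macrophage-like part follows from cell number, since their levels of 67.9 and 85.9 CPM lay below the 149 and 144 CPM of all kept cells, and free RNA in them was not measured. Il10, an anti-inflammatory cytokine, came from dendritic-like cells (46.3%) and macrophage-like cells (43.1%) in unwounded skin, that is 297 and 276 UMIs, and from macrophage-like cells in the wounds, 83.9% and 78.0%. Its level was higher in macrophage-like cells in every condition, 152, 101 and 64.6 CPM against 23.2, 8.33 and 7.51 in dendritic-like cells.

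Regulatory T-like cells of the wounds carried a dividing, metabolically active profile, with Foxp3 a smaller share of their transcripts. All 18 measured proliferation genes were at least 1.5-fold higher on both days, with medians of 1.53 log2 (1.39 to 1.73) and 1.51 (1.38 to 1.71), and Mki67 stood at 107 CPM in unwounded skin against 332 and 307, 3.11-fold (2.34 to 4.20) and 2.87-fold (2.15 to 3.90). The cell cycle genes Ccna2, Kif15 and Pclaf were 7.98-fold (3.34 to 24.97), 8.87-fold (2.94 to 43.8) and 5.61-fold (3.91 to 8.32) higher at day 3, and the histone chaperone Asf1b 14.2-fold (3.79 to 119) higher at day 5. Glycolysis genes were higher by 0.63 (0.47 to 0.81) and 0.72 (0.60 to 0.94), with 8 and 10 of 15 members higher, Hk2, Tpi1, Pgam1 and Eno1 in the lead, and oxidative phosphorylation genes by 0.58 (0.47 to 0.74) and 0.73 (0.54 to 0.80). The hypoxia list, at 0.29 (0.01 to 0.59) and 0.24 (−0.02 to 0.71), was less clear and at day 3 was −0.33 with the k-means caller, and Hif1a itself was 1.43-fold (1.24 to 1.64) and 1.49-fold (1.29 to 1.73) lower. Foxp3, the transcription factor that defines regulatory T cells, was 1.81-fold (1.57 to 2.08) and 1.68-fold (1.45 to 1.95) lower, Gata3 1.71-fold (1.42 to 2.05) and 1.72-fold (1.42 to 2.07) lower, and Il10 1.56-fold (1.07 to 2.23) and 1.89-fold (1.26 to 2.82) lower. Il10 turned to 0.47 and 0.23 log2 higher in cells thinned to 2000 UMIs. The class held 496336 UMIs in 207 unwounded cells, 1753354 in 307 at day 3 and 1314420 in 233 at day 5. UMIs per cell were thus higher in the wounds. A lower CPM of Foxp3, Gata3 or Il10 is a lower share of the RNA. Total UMIs per cell were higher by a larger factor than the CPM of Foxp3 and Gata3 were lower. The mean UMIs per cell of these 2 genes were therefore not lower in the wounds. For Il10 the interval at day 5 leaves this open. The effector list was lower by 0.45 and 0.50, with Icos, Ctla4 and Tgfb1 among 5 and 7 of 15 lower, and the type 17 programme by 1.05 and 1.08, with Stat3, Ccr6, Rora and Ahr among 7 lower on both days.

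Further genes differed between wounded and unwounded regulatory T-like cells. Tff1, Penk and the cytoskeletal Ermn were 9.57-fold (4.95 to 21.2), 7.93-fold (3.93 to 18.7) and 12.6-fold (3.37 to 107) higher at day 5. Thbs1, which leads macrophage cluster 10, was 9.499-fold (4.94 to 20.97) higher at day 3, and 52.0% of that level is what macrophage RNA in the class would give. Camk2n1 and the interleukin 6 receptor Il6ra were 7.07-fold (4.29 to 11.9) and 4.26-fold (3.20 to 5.68) lower at day 3, and Tnfaip2 15.9-fold (6.63 to 46.1) lower at day 5, though level with doublets kept. Il12b was at least 33.0-fold and 24.7-fold lower, but its 28 unwounded UMIs lay in 1 cell; 42 of 47 for Tnip3, 9.22-fold (5.26 to 16.9) lower at day 3, and 101 of 181 for Il1b, 8.12-fold (6.02 to 11.1) lower at day 5, did too. Il1b was 0.97 log2 higher with doublets kept and Tnip3 0.53 log2 higher with the stricter doublet filter. The platelet factor Pf4 was 7.36-fold (5.11 to 10.8) lower at day 5, no more than macrophage RNA in the class would give, with 74 of 114 UMIs in 1 cell, and was 0.16 log2 with the looser cell filter. Areg stood at 544, 609.7 and 429.8 CPM, 1.12-fold (0.980 to 1.29) and 0.790-fold (0.682 to 0.917). Interferon response genes were higher by 0.78 (0.44 to 1.22) and 0.89 (0.46 to 1.41), 7 of 12 and 7 of 11. Immediate early and dissociation stress genes were lower by 0.51 and 0.70, with 4 and 3 of 18 higher and 8 and 11 lower; the day 3 median was 0.21 with the stricter cell filter and 0.15 with doublets kept. RNA at the level of macrophage genes made up 5.12%, 7.53% and 3.39% of the class, and the median-of-ratios scaling would add 0.27 and 0.31 to its values. Foxp3 lies at X:7573644-7595245 (ENSMUSG00000039521) and Mki67 at 7:135689784-135716361 (ENSMUSG00000031004).

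Alpha-beta T-like cells of the wounds were marked by interferon response genes. This list was higher by 1.27 log2 (0.85 to 1.56) at day 3 and 0.97 (0.64 to 1.53) at day 5, with 8 of 12 and 8 of 11 members higher and 0 lower. Ifit1, an interferon-induced inhibitor of translation, was 16.9-fold (4.49 to 142) and 14.7-fold (3.82 to 125) higher. Slfn5 and the chemokine Cxcl10 were 18.7-fold (3.15 to 759) and 8.40-fold (4.58 to 17.1) higher at day 3, with 71 of 178 Cxcl10 UMIs in 1 cell. The heat-shock gene Hspb1 had 0 UMIs in unwounded skin and 37 at day 3, at least 6.40-fold higher, 28 of them in 1 cell. At day 5 Hspa1a was 9.87-fold (5.37 to 20.2), Plac8 24.2-fold (6.47 to 204) and Ly6c2, an antigen of effector and memory CD8 T cells, 8.87-fold (4.14 to 22.7) higher. Areg was 1.99-fold (1.27 to 3.23) and 3.17-fold (2.04 to 5.09) higher, and Mki67 2.44-fold (1.59 to 3.88) and 2.70-fold (1.74 to 4.33). Itga1, the collagen-binding integrin CD49a of resident T cells, was 6.42-fold (2.49 to 19.5) lower at day 3, with Nmt2 4.22-fold (2.61 to 6.996), the activin receptor Acvr2a 4.30-fold (2.16 to 9.003) and the trafficking gene Rab4a 4.04-fold (1.82 to 9.62). At day 5 Acvr2a was 10.6-fold (3.73 to 41.6), Rnpepl1 7.33-fold (2.45 to 29.5), Basp1 4.76-fold (2.09 to 12.2) and the adhesion gene Epcam 4.395-fold (1.80 to 12.2) lower. The residence list was lower by 0.48 and 0.25, and the lists for recirculation (0.50 and 0.49), type 1 and cytotoxic genes (0.50 and 0.64), exhaustion and checkpoint genes (1.15 and 0.92) and proliferation (0.41 and 0.26) were higher. Glycolysis (0.17 and 0.14) and hypoxia (0.12 and −0.18) moved little, as did Ifng (0.796-fold, 0.492 to 1.31, and 0.660-fold, 0.382 to 1.14) and Hif1a (0.925-fold and 0.869-fold). In 19.7%, 22.3% and 35.9% of these cells the CD8b tag was above its cutoff, so the class held more CD8 cells at day 5. Mki67 at day 5 was −0.04 log2 with the looser cell filter, and the proliferation median at day 5 −0.08 with the stricter one. With the k-means caller day 3 values changed sign for Areg (−1.44), Cxcl10 (−0.88), Hspb1 (−0.39), recirculation (−0.89) and glycolysis (−0.47). Ifit1 lies at 19:34640871-34650009 (ENSMUSG00000034459).

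Cluster 9, led by Gzmc, Xcl1, Ctsw and Nkg7, carried more Gzma and Plac8 in the wounds. All 12 NK or ILC1 markers and 9 of 11 dendritic epidermal T markers counted in it. It took no name because another list had more markers among its 10 highest genes. Gzma, the protease granzyme A, stood at 116, 1820.2 and 1860.3 CPM, 15.7-fold (11.9 to 20.98) and 16.02-fold (12.2 to 21.5) higher. As a cell type marker it was not among the genes left out of clustering. Plac8 had 1 UMI in unwounded skin and was 166-fold (29.6 to 6593) and 221-fold (39.3 to 8756) higher. Ifng was 2.53-fold (1.81 to 3.60) and 2.27-fold (1.60 to 3.27) higher, Vegfa, the endothelial growth factor, 2.01-fold (1.40 to 2.94) and 1.65-fold (1.12 to 2.48). Higher too were Csf2, 3.52-fold (1.56 to 9.33) and 5.01-fold (2.24 to 13.2), Mki67 3.02-fold (1.80 to 5.34) and 3.10-fold (1.83 to 5.53), and Hif1a 1.55-fold (1.16 to 2.08) and 1.27-fold (0.932 to 1.74). The serpin Serpinb9b was 45.5-fold (7.92 to 1823) higher at day 3, as was the chemokine Ccl1, 104-fold (18.4 to 4120), with 110 of 164 UMIs in 1 cell. At day 5 Plxnc1 was at least 9.30-fold higher. Lower at day 3 were Serpinb1a (12.3-fold, 6.36 to 26.7), Tiam1 (7.61-fold, 4.402 to 14.0), Rab4a (5.35-fold, 3.25 to 9.16) and Epcam (5.32-fold, 3.27 to 8.99). Lower at day 5 were Styk1 (10.97-fold, 3.92 to 42.5), the T cell factor Bcl11b (7.73-fold, 3.24 to 22.4), Epcam (6.19-fold, 3.52 to 11.6) and the TCR delta constant gene Trdc (5.51-fold, 3.94 to 7.87). Bcl11b was higher with 2 other settings, by 0.08 and 0.25 log2. Ifng and Ccl1 at day 3 were lower with the k-means caller, at −1.40 and −1.31. Areg was 0.848-fold (0.697 to 1.03) and 0.600-fold (0.477 to 0.753).

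In cluster 9 the lists of recirculation and proliferation genes were higher in the wounds, and that of cytotoxic genes with most settings. Type 1 and cytotoxic genes were higher by 0.85 (0.55 to 1.27) and 0.81 (0.52 to 1.23), 8 of 13 on both days, but −0.13 at day 3 with the k-means caller. Recirculation genes were higher by 1.96 (1.40 to 2.51) and 1.35 (0.58 to 2.33), with Ccr7 and Lef1 among the higher members, and proliferation genes by 0.66 (0.50 to 1.08) and 0.97 (0.69 to 1.31). Interferon response genes were higher by 0.47 and 0.67, the former −0.41 with the k-means caller, and residence genes lower by 0.53 and 0.45, with Cxcr6, Itgae and Itga1 lower on both days. Glycolysis, at 0.01 and −0.09, was level, and hypoxia stood at −0.09 and −0.48, the latter turning to 0.06, 0.20, 0.16 and 0.00 with 4 other settings. Cells with no receptor tag were 43.3%, 61.8% and 54.8% of the cluster. Cells with the TCR beta tag and neither or both of CD4 and CD8b were 38.1%, 25.9% and 33.9%. Those with the TCR gamma-delta tag alone were 13.4%, 7.65% and 4.03%. So the makeup of the cluster differed too, and the lower Trdc at day 5 was not told apart from it. Scaling by median of ratios would add 0.17 and 0.13 to its values. Gzma lies at 13:113093825-113100981 (ENSMUSG00000023132), Plac8 at 5:100553725-100572245 (ENSMUSG00000029322) and Vegfa at 17:46016993-46032369 (ENSMUSG00000023951).

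Macrophage-like cells of the wounds carried more transcripts of glycolysis, hypoxia and interferon genes, together with their change of clusters. Plac8 was 48.5-fold (25.5 to 106) and 61.7-fold (32.4 to 135) higher, Ms4a4c 26.5-fold (17.5 to 42.3) and 32.2-fold (21.2 to 51.4), the monocyte marker Ly6c2 151-fold (41.6 to 1244) at day 5, and osteopontin, Spp1, 31.2-fold (21.1 to 48.2) at day 3. The matrix glycoprotein Thbs1, which leads cluster 10, was 21.8-fold (17.9 to 26.8) and 23.6-fold (19.4 to 29.1) higher. Vegfa stood at 19.3, 124 and 148 CPM, 6.41-fold (4.60 to 9.23) and 7.66-fold (5.47 to 11.04), Hif1a was 1.56-fold (1.31 to 1.86) and 1.21-fold (1.01 to 1.45) and Mki67 3.42-fold (2.47 to 4.88) and 2.52-fold (1.80 to 3.63) higher. The phospholipase Pla2g2d was 75.4-fold (49.6 to 119) lower at day 3, the gelatinase Mmp9 65.9-fold (43.1 to 105) and 110-fold (52.0 to 277), and Cd209f and Cd209b, lectins that lead cluster 13, 17.9-fold (14.9 to 21.6) and 21.8-fold (16.8 to 28.6) and, at day 5, 23.6-fold (18.6 to 30.3). Mucl1, which leads dendritic cluster 3, was 72.9-fold (57.7 to 93.1) and 22.5-fold (18.5 to 27.6) lower, with 192 of 598 unwounded UMIs in 1 cell. Tnf was 2.15-fold (1.87 to 2.47) and 2.63-fold (2.25 to 3.08) lower and Il10 1.51-fold (1.32 to 1.71) and 2.36-fold (2.03 to 2.73) lower. Interferon genes were higher by 1.67 (1.45 to 1.81) and 1.53 (1.43 to 1.87), 11 of 14 on both days, glycolysis genes by 0.77 (0.65 to 0.86) and 0.86 (0.71 to 0.94), and hypoxia genes by 0.61 (0.48 to 0.72) and 0.51 (0.40 to 0.74). Also higher were lipid genes by 0.61 and 0.47 and proliferation genes by 0.32 and 0.78, and repair factors were lower by 0.47 and 0.54. In the largest cluster alone, of macrophage-like and of dendritic-like cells, 31 of 50 gene values left their interval, 12 more changed sign and 7 stayed within it, and the largest macrophage-like cluster, cluster 2, held only 14 unwounded cells. There Hif1a was −0.09 and −0.29, and Mmp9, Mucl1 and Cd209b were no longer lower, at 0.32 and 0.63, at 0.17 and 0.18, and at 0.18.

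Dendritic-like cells of the wounds had more proliferation transcripts, together with a change of clusters. Clusters 15 and 20, with histone genes among their 10 leading genes, were 74 of 1735 cells in unwounded skin, 82 of 476 at day 3 and 68 of 315 at day 5. Proliferation genes were higher by 2.10 (2.02 to 2.19) and 1.60 (1.50 to 1.70), 18 and 17 of 18, with the mitotic ubiquitin-conjugating enzyme Ube2c 7.71-fold (6.92 to 8.61) and 6.98-fold (6.21 to 7.86) and Mki67 2.68-fold (2.48 to 2.91) and 2.70-fold (2.47 to 2.96) higher. Hspa1a was 7.94-fold (7.39 to 8.53) and 6.61-fold (6.12 to 7.15) and Hspb1 20.4-fold (15.7 to 27.0) and 19.8-fold (15.04 to 26.4) higher, with 176 of 607 Hspb1 UMIs of day 3 in 1 cell. Plac8 was 10.96-fold (8.97 to 13.5) and 17.1-fold (14.0 to 21.1) higher. Vegfa was 2.90-fold (2.53 to 3.33) and 2.50-fold (2.12 to 2.94) and Areg 3.88-fold (3.36 to 4.50) and 2.98-fold (2.50 to 3.54) higher. The resistin-like gene Retnla, the lysozyme Lyz1, Flt1 and Ehf lead cluster 3, the main dendritic cluster of unwounded skin, and were lower. Retnla was lower 14.0-fold (11.9 to 16.5) and 24.4-fold (18.8 to 32.3), Lyz1 7.15-fold (6.67 to 7.68) and 14.9-fold (13.1 to 16.9), Flt1 7.44-fold (5.74 to 9.80) at day 3 and Ehf 10.7-fold (7.64 to 15.6) at day 5. The haem oxygenase Hmox1 was 6.65-fold (6.05 to 7.33) and 9.31-fold (8.09 to 10.8) lower and Il10 2.79-fold (2.07 to 3.82) and 3.09-fold (2.11 to 4.70). Oxidative phosphorylation was higher by 0.62 and 0.54, hypoxia by 0.49 and 0.53, glycolysis by 0.44 and 0.42 and interferon response by 0.74 and 0.93. The type 17 programme was lower by 0.76 and 0.73, its day 5 value turning to 0.02 with every member that had 1 UMI in each condition. The median of all genes was itself 0.17 on both days and the median-of-ratios scaling would take away 0.28 and 0.26. Within the largest cluster alone Hspb1 was lower by 0.45 and 0.32, Ube2c at day 3 by 0.54 and Plac8 at day 5 by 0.37, and Il10 at day 3 was level at 0.07. With clusters 5 and 8 counted as dendritic-like the proliferation median was 1.33 and 0.88 and Il10 −0.18 and −0.22.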

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

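The tests of median depth, of single cells, of the Areg level over all cells and of macrophage RNA were chosen only after the result was seen. The bound and the grouping by class of the macrophage RNA test were also set after its values were seen.

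The second sequencing run is used in no comparison, and its barcode list still carries a signal, since 17430 of its 18727 barcodes are also in run 1, which has 17432. Its counts were not analysed here.

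Most kept cells were myeloid although the gate was set on CD90.2. The CD3 genes reached at most 0.949% of their lymphoid level in the myeloid classes together and 1.09% in a single class. So the cells counted as myeloid carried little T cell RNA. Part of this follows from selection, since Scrublet and the naming rule took out cells and clusters with RNA of both lineages. Cluster 21, with markers of both, was left out in this way. These values therefore cannot exclude doublets of a myeloid cell with a T cell among all barcodes. Thy1, which encodes CD90, reached at most 1.81% in these together and 2.44% in a single class, which argues against myeloid cells that transcribe it themselves. The median UMIs of cells counted as myeloid were at least 1.84 times those of lymphoid cells in each condition. For these cells depth argues against droplets of free myeloid RNA alone. Selection plays a part here too, since the gene filter took out shallow barcodes. The naming rule left out the shallow cluster 19 (median 1156 UMIs), whose best list was that of macrophages. Depth therefore cannot exclude such droplets among all barcodes. Antibody held on the surface of myeloid cells, a loose gate and a true population stay open and were not tested.

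Areg was higher in gamma-delta T-like cells at day 3. Without the top cell of each condition the ratio was 7.52 (5.39 to 10.8), which argues against a single cell. Among cells with the gamma-delta tag alone it was 15.04 (10.8 to 21.6), which argues against a changed share of TCR beta tag cells in the class. Other gamma-delta cells pass the same gate, as did 105 of 112 dendritic epidermal T-like cells. The test therefore cannot tell whether their share in the class changed. The level over all kept cells at day 3 was 9.53% of that of the class, which argues against free RNA. A response to the wound stays open as a hypothesis, beside effects of the digestion and of the single pool per condition, which were not tested. The ratio also changed sign with the k-means hashtag caller, on few cells, so its dependence on the calling of conditions stays open too.

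The interferon response list was higher in wounded lymphoid classes, which RNA from macrophages could explain in part. After the macrophage profile was subtracted from the wounded condition alone, the alpha-beta T-like class kept at least 0.906 of the median, with lower bounds of 0.836 and 0.865, which argues against macrophage RNA as the main cause there. The share left on the lower of the 2 days was 0.718 in the gamma-delta T-like class, 0.524 in the regulatory T-like class and 0.826 in cluster 9. On the other day it was 0.951, 0.702 and 0.946. Lower bounds were under 0.5 on at least 1 day (0.378 and 0.406, 0.191 and 0.474, 0.405 and 0.750). Subtracted from both conditions, the macrophage profile left 1.07 and 0.861 (lower bounds 0.717 and 0.631), 0.578 and 0.709 (0.313 and 0.572) and 1.09 and 1.17 (0.748 and 0.967) at day 3 and day 5, in the same order of classes. Since the 2 subtractions differ in part and the second was chosen after the first was seen, a response of the cells and macrophage RNA cannot be told apart in these 3 classes, and a biological difference stays open and untested.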

How the results depend on the processing

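HTODemux with clara, the stricter Scrublet score, the gamma-delta tag alone, the sums without the top cell and clusters 5 and 8 counted as dendritic-like were chosen only after the result was seen. Values below are log2 ratios over unwounded skin unless given as percent. A value is called reversed where its interval in the main analysis excluded 0 and its sign changed, and moved where it otherwise left that interval, taken for genes on the scale with 5 CPM added. So a value near 0 that changed sign counts as moved or as the same. For each change the cause was not tested unless it is stated. No paired analysis was possible because each condition is 1 pool and the labels give no animals.

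Over all alternatives, 2045 of 2138 gene values, 958 of 1022 list values and 160 of 188 shares kept their direction. The dendritic-like share stayed lower, at −2.51 to −1.11 at day 3 and −2.33 to −0.91 at day 5, and the macrophage-like share higher, at 1.18 to 1.88 and 0.89 to 1.73. The gamma-delta T-like share stayed lower at day 5, at −1.55 to −0.53, while at day 3 it ran from −1.003 to −0.0440, the latter near 0. In gamma-delta T-like cells glycolysis stayed higher, at 0.26 to 0.65 and 0.20 to 0.39, and hypoxia at day 5, at 0.16 to 0.45, while hypoxia at day 3 ran from 0.00982, near 0, to 0.41. Il17f and Hif1a at day 5 stayed lower, at −1.15 to −0.23 and −1.02 to −0.28. Apart from HTODemux with k-means, Il17a at day 3 stayed higher, at 0.74 to 1.97. At day 5 the TCR beta tag held 57.3% to 65.3% of Il17a and 74.0% to 77.6% of Il17f UMIs. With median-of-ratios scaling, Leiden resolutions 0.5 and 2.0 and sums without the top cell, no value whose interval excluded 0 changed sign. Others near 0 did, among them hypoxia at day 3 (−0.09 to 0.06) and glycolysis at day 5 (−0.09 to 0.04) in cluster 9 with median-of-ratios scaling.

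HTODemux with k-means called 1019 barcodes of day 3 single and kept 11.1% of the other caller's, since its cutoff lies inside the upper mode. Its day 3 values rest on these cells, few of which were gamma-delta T-like. A negative value in that class can come from an absence of counts. Shares at day 3 moved to −1.66 for lymphoid, −2.03 for dendritic-like, 0.74 for regulatory T-like, −0.71 for alpha-beta T-like (from 0.14, with an interval on both sides of 0) and −1.003 for gamma-delta T-like cells. The dendritic epidermal T-like share reversed to 0.22. The lymphoid share at day 5 moved to 0.0884. In gamma-delta T-like cells at day 3 Il17f moved to −1.24 and the type 17 cytokines to −3.40. Reversed there were Il17a at −6.44, Cysltr1 at −1.93, Sgip1 at −2.30, Id3 at −3.61, Areg at −5.31, Calca at −2.30, Gzmc at −2.60, Neil1 at −1.43, Rarg at 0.68 and Zdhhc23 at −1.93. The lists of tissue residence (−0.15), immediate early genes (−0.71) and interferon response (−0.0431) also reversed. At day 5 Il17a reversed to −0.40 and Penk to −0.64, and day 5 over day 3 Il17f to 0.13 and Areg to 6.53. In alpha-beta T-like cells at day 3 Areg (−1.44), Cxcl10 (−0.88), Hspb1 (−0.39), glycolysis (−0.47) and recirculation (−0.89) reversed. So did hypoxia (−0.33) in regulatory T-like cells and, in cluster 9, Ifng (−1.40), Ccl1 (−1.31), type 1 genes (−0.13) and interferon response (−0.41). The gamma-delta T-like class held 85.5% of Il17a UMIs in unwounded skin and 45.18% at day 5. Cluster 16 held 0% of Il22 at day 5. Of Il17a in unwounded skin the gamma-delta tag held 45.1% and the beta tag 12.6%.

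With the top hashtag at least 5 times the second, the alpha-beta T-like share at day 5 moved to 0.55 and Il17a in gamma-delta T-like cells at day 3 to 0.79. Il17a at day 5 reversed to −0.18, Penk to −0.75 and proliferation at day 3 to 0.0643. The class held 85.2% of Il17a in unwounded skin and 81.25% at day 3. Cluster 16 had no counterpart and so 0% of Il22 on both days, here and with clara, 200 genes and doublets kept, and at day 5 with 1000 genes.

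With clara the lymphoid share at day 5 moved to 0.0767, the macrophage-like share to 1.88 and 1.71 and cluster 9 to 0.40 and 0.53. In gamma-delta T-like cells at day 5 Il17a moved to 0.25 and the type 17 cytokines to −1.41, and Cldn5 reversed to 0.77 and the type 17 programme to 0.00512. In cluster 9 at day 5 Bcl11b reversed to 0.0782 and hypoxia to 0.0626. The class held 91.9% of Il17a in unwounded skin and 83.1% at day 3, and the gamma-delta tag 80.6% in unwounded skin.

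With at least 200 genes and at most 20% mitochondrial UMIs, cluster 9 at day 5 moved to 0.32 and Il17a in gamma-delta T-like cells at day 3 to 0.81. At day 5 Il17a reversed to −0.15, Penk to −0.74 and Mki67 to 0.0626. Proliferation reversed to 0.15 at day 3 and 0.34 at day 5. Pf4 in regulatory T-like cells (0.16), Mki67 in alpha-beta T-like cells (−0.0416) and hypoxia in cluster 9 (0.20) reversed at day 5. The class held 88.2% of Il17a in unwounded skin and 82.8% at day 3.

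With at least 1000 genes and at most 5% mitochondrial UMIs, shares at day 3 and day 5 moved to 0.24 and 0.54 for lymphoid, 1.87 and 1.73 for macrophage-like, and 0.67 and 0.53 for regulatory T-like cells. They moved to 0.25 and 0.45 for cluster 9 and −0.92 and −1.20 for ILC2-like cells, and to −0.27 for alpha-beta T-like cells at day 3. In gamma-delta T-like cells at day 5 Il17a moved to 0.00318 and the type 17 cytokines to −1.15, and Jun reversed to 0.30 and Cldn5 to 0.89. Immediate early genes in regulatory T-like cells at day 3 reversed to 0.21 and proliferation in alpha-beta T-like cells at day 5 to −0.0834. The class held 92.2% of Il17a in unwounded skin and 83.0% at day 3, and the gamma-delta tag 79.8% of Il17a and 90.5% of Il17f in unwounded skin.

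With doublets kept, shares at day 3 moved to 0.10 for lymphoid, 1.57 for macrophage-like, 0.45 for regulatory T-like and −0.20 for alpha-beta T-like cells. At day 5 they moved to 1.42 for macrophage-like cells, 0.46 for cluster 9 and −0.62 for ILC2-like cells. Il17a in gamma-delta T-like cells moved to 0.74 and 0.0658. The class held 89.5% of Il17a in unwounded skin and 78.1% at day 3. In regulatory T-like cells Il1b (0.97) and Tnfaip2 (0.0330) at day 5 and immediate early genes (0.15) at day 3 reversed, and in cluster 9 at day 5 Bcl11b (0.25) and hypoxia (0.00193). With the stricter Scrublet score the ILC2-like share at day 5 moved to −0.68. Penk in gamma-delta T-like cells at day 5 (−0.82) and Tnip3 in regulatory T-like cells at day 3 (0.53) reversed.

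With all variable genes the macrophage-like share moved to 1.54 and 1.37 and the alpha-beta T-like share at day 3 to −0.25. From surface tags the gamma-delta T share at day 5 moved to −1.55. With list members of 1 UMI in each condition the type 17 cytokines of gamma-delta T-like cells moved to 0.42 at day 3 and reversed to 0.0764 at day 5. The type 17 programme of dendritic-like cells at day 5 reversed to 0.0185. With members of at least 100 UMIs the type 17 cytokines at day 3 moved to 0.42 and hypoxia in cluster 9 at day 5 reversed to 0.16. In cells thinned to 2000 UMIs Il10 of regulatory T-like cells reversed to 0.47 and 0.23. With the gamma-delta tag alone Il17a at day 3 moved to 1.97, Il17f at day 3 to 0.87, hypoxia at day 3 to 0.00982 and the type 17 cytokines at day 5 to −0.81. With clusters 5 and 8 counted as dendritic-like the dendritic-like share moved to −1.11 and −0.91 and the macrophage-like share to 1.18 and 0.89, and no gene or list value changed sign. In the largest macrophage-like cluster alone Mmp9 reversed to 0.32 and 0.63, Hif1a to −0.0934 and −0.29, Mucl1 to 0.17 and 0.18 and Cd209b at day 5 to 0.18. In the largest dendritic-like cluster Il10 (0.0704) and Ube2c (−0.54) at day 3, Hspb1 (−0.45 and −0.32) and Plac8 at day 5 (−0.37) reversed.

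Some alternatives gave no value. HTODemux with k-means had no counterpart of the ILC2-like class and cluster 16, and under 20 Il17a and Il17f UMIs at day 3. Genes, lists and cytokine sources were not rerun with other Leiden resolutions or all variable genes. Depth limits the small classes, with 3 UMIs as the limit of a value of 0. The gamma-delta T-like class had 54 cells and 211376 UMIs at day 5, the dendritic epidermal T-like class 10 cells and 27172 UMIs at day 5, and cluster 16 had 18 cells and 52794 UMIs in unwounded skin.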

Other observations

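The ILC2-like class, with 62, 78 and 59 cells, was described only after its values were seen. Proliferation genes were higher by 2.39 log2 (1.94 to 2.71) at day 3 and 1.72 (1.02 to 2.10) at day 5, with 16 of 16 and 8 of 11 measured members at least 1.5-fold higher. Mki67 was 6.68-fold (2.94 to 18.7) and 3.88-fold (1.62 to 11.3) higher. Areg stood at 1031, 1856 and 1328 CPM, 1.80-fold (1.54 to 2.11) and 1.29-fold (1.09 to 1.53) higher. Il5 stood at 1134, 1296 and 1061 CPM and Il13 at 226, 367 and 216 CPM. Cells above the CCR6 tag cutoff were 30.6%, 48.7% and 66.1% of the class, with medians of 41, 47 and 53 counts around a cutoff of 47.5, so a small shift carries these shares. Cells with the TCR beta tag were 42.4% of the class at day 5.

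The CCR6 tag differed in direction between other lymphoid classes. Cells above its cutoff were 76.8%, 82.7% and 90.7% of gamma-delta T-like cells and 85.5%, 72.3% and 62.7% of regulatory T-like cells in unwounded skin, day 3 and day 5. The medians were 55, 66.5 and 83 counts and 73, 63 and 56. The difference between the classes was not tested, and over 97% of wound macrophage-like cells also lay above this cutoff. Keratinocyte-like cells were 2.11%, 1.36% and 0.479% of kept cells and fibroblast-like cells 1.75%, 2.02% and 1.70%. Hspa1a, a heat shock gene, was higher at day 3 in gamma-delta T-like (13.8-fold), regulatory T-like (5.23), alpha-beta T-like (7.46), cluster 9 (4.01), macrophage-like (2.31) and dendritic-like cells (7.94). It was lower in the small dendritic epidermal T-like class (0.109-fold, 0.00262 to 0.680).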
